A study of Mus musculus with 4 samples.

How the data were processed

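Total RNA came from the ipsilateral brain hemisphere of mice in which the left middle cerebral artery had been closed for good by electrocoagulation, a model of focal stroke without reperfusion. The mice were wild type (WT) or lacked TNFRI (KO), a receptor for the cytokine tumour necrosis factor. Per the labels' protocols, the RNA was DNase-treated, reverse transcribed with a radioactive nucleotide and hybridised to a Clontech Atlas mouse cDNA array, on which each cDNA is a spot. The labels give 4 samples, 1 for each genotype at 3 h and at 6 h, and 2 hybridisation files for each sample, 8 in all. The series text speaks of 2 mice per genotype and time, but each sample record describes its files as duplicate hybridisations. The hybridisations were therefore treated as technical repeats and averaged, and a group holds 1 sample. If the files of a pair came from different mice, the spread between them would also hold animal variation; the labels do not settle this.

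The deposited hybridisation files hold 1 intensity per ID on a linear scale for 597 IDs. Image software, background subtraction and filters are not given in the sources used here. No value lies at or below 0. Blanks occur in 3 of the 4 files at 6 h and in none at 3 h. The authors' deposited series table holds a ratio per ID. From the values it is each intensity divided by the mean of its hybridisation, then averaged over the duplicates of a sample. Recomputing it this way matched all listed values to a relative tolerance of 1e-06 in the WT 3 h, KO 3 h and WT 6 h columns. In the KO 6 h column 51 values matched, 1 differed 3.23-fold and the others differed by at most 0.486%. The table was used as an alternative only.

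All 8 files list the IDs in the same order. The design, fixed before the data were examined, averaged duplicates per ID. The duplicates were found not to correlate by ID, so regular grid orders of the 588 spots that precede the last 9 IDs were searched for one that lines up the second hybridisations with the first. The search covered 6451 distinct orders, made by splitting the list into up to 4 nested dimensions and permuting or mirroring them. It used only the agreement between the averages of the 4 first and the 4 second hybridisations, and no genotype or time. In a check on simulated data it recovered all 20 of 20 known orders. Those orders were drawn from the orders searched, with noise smaller than the signal. The check therefore cannot show what the search returns if the true order is not among them. All results use the best order, which exchanges rows and columns within each of 6 blocks of 7 by 14 spots. This choice was made after seeing the data, and counts with pairing by deposited ID are given beside those by position. A spot is named by its ID in the first hybridisations. Which set of files has the right IDs is not known.

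The files do not pair the IDs with genes, and no table used here does. No gene is named, so Tnfrsf1a, which encodes TNFRI, could not be located as a check of the genotype labels. The gene lists, the cell type markers and the scaling on housekeeping genes planned before the data were examined were not run. Of the spots past a test, at most 2 that rose and 2 that fell are named, those with the largest change, in place of the longer lists planned.

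Intensities were background-corrected with normexp and an offset of 50 within each hybridisation, taken to log2 and quantile-normalised across the 8 hybridisations in limma 3.58.1 under R 4.3.3. Blanks were left out. A spot was tested if both hybridisations of at least 1 sample had a value, which all 597 did. Duplicates were averaged to 1 value per sample. Differences across both times or both genotypes were tested with limma (lmFit and eBayes) in an additive model of genotype and time over the 4 samples. That model leaves 1 residual degree of freedom, moderated across spots with 14.7 prior degrees of freedom. Its residual is the genotype by time difference. The SEs and p-values are therefore not computed from the spread between duplicates. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. In 20 simulated data sets of 597 spots for the KO and WT comparison over both times, with 100 spots changed, the test recovered 2.5% of spots changed by 1 on the log2 scale, 49.7% of those changed by 2 and 96.6% of those changed by 3. With no change it made 0.2 false calls on average. The simulated noise was independent between spots and drawn from the fitted model, without block effects or blanks. These rates therefore need not hold for the arrays.

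Within 1 time or genotype there is 1 sample per group and no test. A size rule was used instead, fixed before the data were examined. It asks for a difference of at least 2-fold between sample means, no overlap between the hybridisations of the 2 samples, and values above the array median in both hybridisations of the higher sample. If the arrays of a comparison were exchangeable, chance would give no overlap in 33.3% of spots. Differences between the first and second hybridisations can lower that share, so 33.3% is a reference and not a chance level. SDs are over 2 hybridisations and are technical. Correlations are across spots, which are not independent replicates, with 95% intervals from Fisher's transformation or from 2000 bootstrap draws of spots, as stated.

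Alternatives covered median scaling, no scaling between hybridisations, larger and smaller offsets, filters on dim spots, the authors' table, single hybridisations and leaving out each hybridisation. Others were leaving out each sample together with the second factor, a fit without the second factor, and other variance options. A further fit kept the hybridisations apart, with the sample as a block and the hybridisation number as a factor. Pairing by deposited ID, as planned, became an alternative once position was used. Blanks set to 0, values taken as already background-corrected (with an offset of their own), these 2 together, scaling on the last 9 spots, block medians made equal across hybridisations after quantile normalisation, and spots with all 8 values were added after seeing the data. The order search and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. The number of arrays limits the precision.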

Results

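Gene expression in the ischemic hemisphere was measured on spotted cDNA arrays in WT and TNFRI KO mice at 3 h and 6 h after permanent middle cerebral artery occlusion. The comparisons address how expression in the ischemic hemisphere differs without TNFRI and between the times. No sample came from a hemisphere without occlusion. A difference in the response to ischemia therefore cannot be told from a genotype difference present before it. Each of the 4 groups held 1 sample with 2 hybridisations, called here the first and the second. Total intensity per hybridisation ran from 1504340 in the first WT 3 h array to 10275600 in the second KO 3 h array. The median spot intensity was 1578 and 2514 in WT at 3 h, 2949 and 14144 in KO at 3 h, 2598 and 2459 in WT at 6 h, and 2192 and 1736 in KO at 6 h.

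The low end of the intensities differed between the times. At 3 h the dimmest spot stood at 13.2% to 32.2% of the array median and no ID was blank. At 6 h the dimmest spot stood at 0.480% to 0.974% of the median, and 39 and 10 IDs were blank in the WT arrays and 51 and 0 in the KO arrays. Of the 51 blanks in the first KO array, 42 lay in 1 block of the array, block 6 of those described below. The brightest spot was 22.3 to 68.0 times the median at 3 h and 234 to 396 times at 6 h. Every 3 h array thus differed from every 6 h array in its dynamic range, so time and this property of the files cannot be separated.

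The same ID did not mark the same spot in the first and second hybridisations. Across IDs, log2 intensities of duplicates correlated at r = 0.08 to 0.13 in the 4 samples. Arrays of different samples within the first or within the second set correlated at r = 0.48 to 0.79. Averaged over the 4 samples, the 588 spots that precede the last 9 IDs correlated between the sets at r = 0.0034 in the deposited order. Exchanging the rows and columns within each of 6 blocks of 98 spots raised this to r = 0.79, against 0.43 for the next best of 6451 orders. By block, r rose from between -0.09 and 0.15 to between 0.70 and 0.87. The 9 IDs that close the list, M901 to M909, correlated at r = 0.98 as deposited. In the deposited order, 12 of the 588 spots hold the same position in both sets. The authors' deposited table averages the duplicates by ID, so for the other IDs its values are means of 2 different spots.

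**Figure D1:**
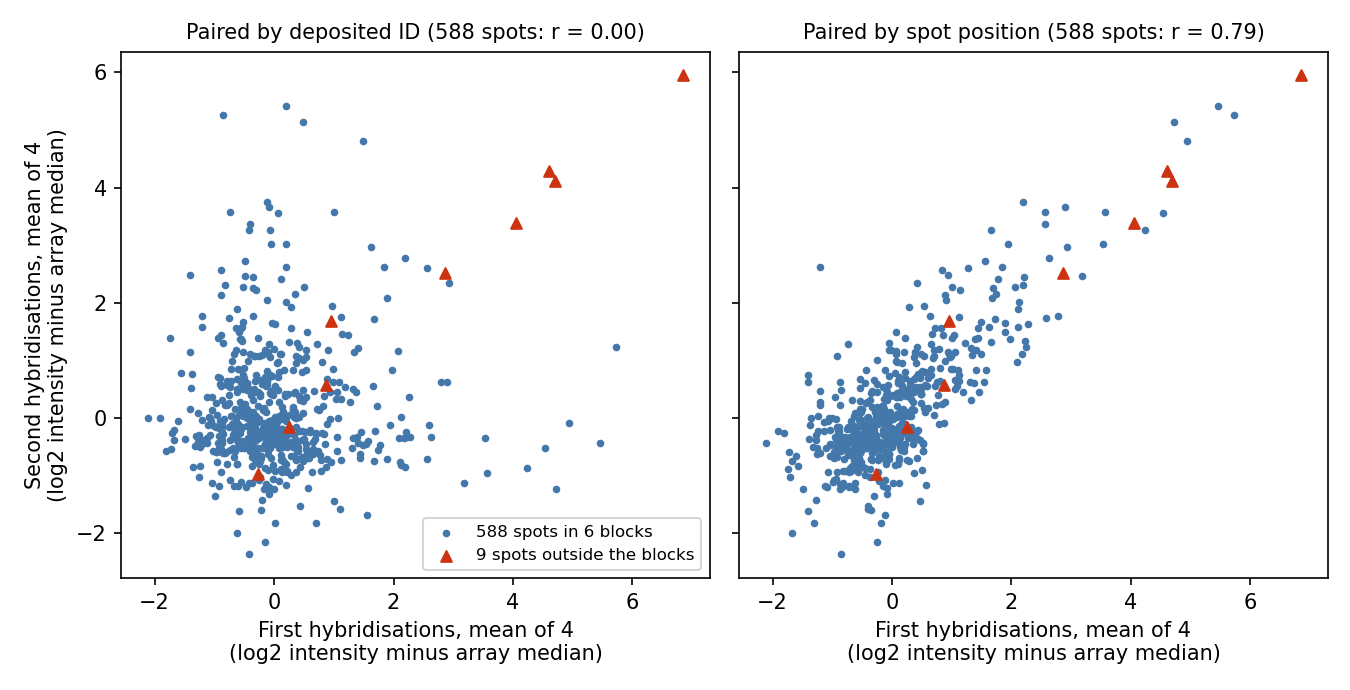
Mean log2 intensity minus the array median per spot, in the first (x axis) and second (y axis) hybridisations, each over 4 arrays. Left, the 588 spots in blocks paired by deposited ID (r = 0.0034); right, paired by position (r = 0.79); triangles are the 9 spots outside the blocks, whose values are the same in both panels.

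Paired by position, duplicates of 1 sample correlated at r = 0.52 to 0.68 (median 0.62). Arrays of different samples from different sets correlated at r = 0.39 to 0.81 (median 0.59). The highest, 0.81, joined the second WT 3 h array and the first KO 3 h array and lay above every pair of duplicates. The first WT 3 h array and the second KO 3 h array correlated at r = 0.57. That lay below the WT duplicates at 3 h (0.68) and above the KO duplicates at 3 h (0.52). The median SD of a spot between duplicates, after normalisation, was 0.67 in WT and 0.66 in KO at 3 h, and 0.65 in WT and 0.52 in KO at 6 h, on the log2 scale.

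In the comparison of KO with WT over both times, which asks for changes shared by 3 h and 6 h, no spot rose or fell. By limma, 0 of 597 spots passed the threshold, and the smallest adjusted p was 0.994. At an unadjusted p under 0.05 there were 16 spots, where chance gives 29.85. The median SE of a spot's difference was 0.537 on the log2 scale, so changes near 2-fold were not detectable with these arrays. With pairing by deposited ID the count was also 0. Single calls appeared under some alternatives: 1 with the first hybridisations only, 1 with trend and robust variance options, 1 with values taken as already background-corrected, whether blanks were left out or set to 0, 1 without the second KO 3 h array, and 1 without the WT 3 h sample and the time factor.

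At 3 h, 30 spots met the size rule, 19 higher and 11 lower in KO than in WT, against 28 with pairing by deposited ID. The largest difference upwards was 2.40 on the log2 scale, from 8.72 ± 0.02 (SD, n = 2 hybridisations) in WT to 11.13 ± 0.06 in KO, and the largest downwards was -1.97, from 11.72 ± 0.65 to 9.75 ± 0.81. The hybridisations of KO and WT did not overlap in 21.4% of spots, where exchangeable arrays would give 33.3%. Exchanging the genotype of the second KO and WT arrays gave 82 spots, and splitting the 4 arrays by set gave 86. The difference in the first hybridisations and that in the second correlated negatively across the 597 spots (r = -0.28, 95% interval -0.35 to -0.21; rho = -0.25). In the first hybridisations the difference followed position on the array: 47.7% of its variance lay between the 6 blocks, with 95.9% of spots above 0 in block 3 and 7.14% in block 4. In the second hybridisations 13% lay between blocks. With block medians made equal across the arrays, 16 spots met the rule, 8 in each direction. With values taken as already background-corrected, 4 met it, 1 higher and 3 lower. The direction split also depended on the arrays used: it was 13 higher and 40 lower without the first WT array, 54 and 89 without the second, 66 and 43 without the first KO array and 61 and 20 without the second. A shift towards the sample left with 1 array is built in, since the rule is easier to meet for that sample. The direction split depended on scaling too: 63.3% of the 30 spots were higher in KO after quantile normalisation, 35.1% of 37 after median scaling, 98.3% of 60 after scaling on the last 9 spots and 100% of 125 without scaling. These scalings moved the median difference of all spots to -0.30, 0.62 and 1.6 on the log2 scale, in that order.

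At 6 h, 33 spots met the size rule, 18 higher and 15 lower in KO, against 21 with pairing by deposited ID. The largest upwards was 4.18 on the log2 scale, at 11.49 ± 0.12 in KO against 7.31 in the 1 WT array that gave a value. The largest downwards was -1.81, from 12.02 ± 0.79 in WT to 10.21 ± 0.99 in KO. The hybridisations did not overlap in 28.3% of the 508 spots with all 4 values. Exchanging the genotype of the second arrays gave 16 spots and splitting by set gave 100. The differences in the first and second hybridisations did not correlate clearly (r = -0.06, 95% interval -0.14 to 0.03, rho = -0.04). With block, row and column effects removed, r was -0.12 (95% interval -0.22 to -0.019) over 499 spots, so a weak negative correlation also appeared at 6 h. In block 6, which held most blanks of the first KO array, the median difference in the first hybridisations was -1.40, with 16.7% of 54 spots above 0, against 0.0071 and 51% of 98 in the second. The split was 15 higher and 44 lower, or 41 and 90, without the first or second WT array, and 44 and 15, or 55 and 27, without the first or second KO array. As at 3 h, a shift towards the sample left with 1 array is built in. With block medians made equal, 22 spots met the rule, 12 higher and 10 lower. With values taken as already background-corrected, 5 met it, 4 higher and 1 lower. Of the 43 spots that met the rule without scaling, 11.6% were higher in KO, against 54.5% after quantile normalisation. Without scaling the median difference of all spots was -0.45, and with scaling on the last 9 spots it was 0.11.

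**Figure D2:**
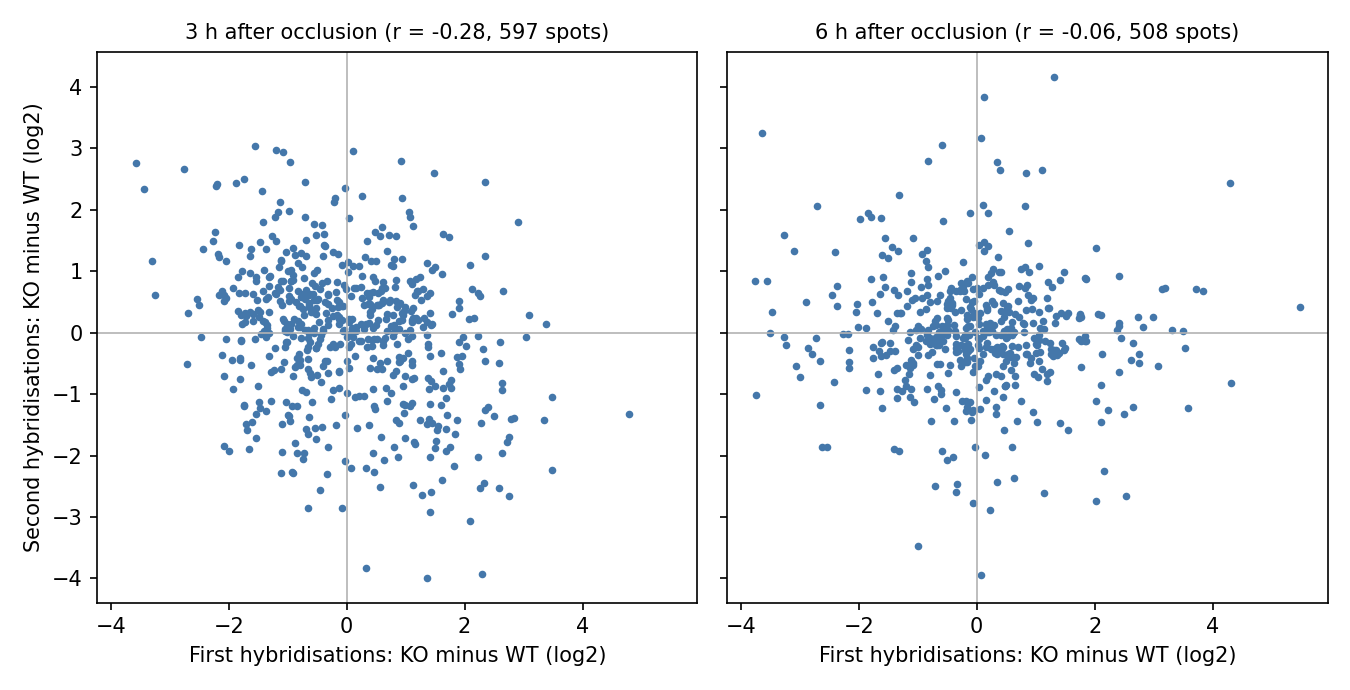
KO minus WT per spot on the log2 scale in the first (x axis) and second (y axis) hybridisations, paired by position, at 3 h (left, 597 spots) and 6 h (right, 508 spots with 4 values). Each point is a spot; the differences correlate at r = -0.28 at 3 h and r = -0.06 at 6 h.

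The genotype differences at the 2 times shared few spots. Upwards, 1 spot met the rule at both times, where independent lists give 0.573, and none met it downwards at both, where they give 0.276. These values are not chance levels, since the rule draws both lists from bright spots. The differences of sample means at 3 h and 6 h, which share no array, correlated at r = -0.08 (95% interval -0.16 to 0.0048, rho = -0.07). Neither difference repeated between the duplicates of its own time, as given above. Little sharing between the times therefore cannot show that the genotype difference changed from 3 h to 6 h.

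In the comparison of 6 h with 3 h over both genotypes, 11 spots rose and 5 fell of 597 by limma at an adjusted p under 0.05, and 107 had an unadjusted p under 0.05, where chance gives 29.85. Changes ran from 2.12 to 3.78 for spots that rose and from -2.30 to -3.17 for spots that fell, on the log2 scale. The 2 that rose most were the spot listed as M810 in the first hybridisations (3.78, SE 0.63, limma adjusted p = 0.00828) and that listed as M309 (3.11, SE 0.61, limma adjusted p = 0.0140). The 2 that fell most were M518 (-3.17, SE 0.55, limma adjusted p = 0.00828) and M362 (-2.71, SE 0.64, limma adjusted p = 0.0328). M810 was higher at 6 h in 4 of 4 array pairs, by 1.23 and 3.55 in WT and 5.14 and 5.19 in KO. M309 changed by -0.77 in the first WT pair and was higher by 2.91 to 5.77 in the other 3. M518 was lower in 4 of 4 pairs, but its deposited intensities in the KO 3 h duplicates were 1231.13 and 315136.01. The SD of M518 between duplicates was 2.28 in WT and 6.76 in KO at 3 h, and 0.96 and 3.23 at 6 h. Its SE of 0.55 does not take in this spread. M362 was lower in the 3 pairs that could be compared and blank in the first KO 6 h array, in block 6, where most of that array's blanks lay. Each of the 4 lost its call when certain single arrays were left out. M518 was -0.78 (limma adjusted p = 0.654) without the second KO 3 h array, -5.56 (0.196) without the first, and -2.37 (0.0752) without the second WT 3 h array; without the first KO 6 h array it kept its call at -2.03 (0.0371). M362 was -1.28 (0.655) without the second KO 6 h array, and its adjusted p was 0.239 without the first KO 3 h array, 0.0855 without the second WT 6 h array and 0.0748 without the second WT 3 h array. M309 was 2.06 (0.325) without the second WT 6 h array, and its adjusted p was 0.204 without the first KO 3 h array. For M810 the adjusted p was 0.117 and 0.159 without these 2 arrays, in that order. In all, 10 of the 16 spots moved one way in 4 of 4 pairs, 3 had at least 1 pair reversed and 3 had a blank. Most of the 11 spots that rose, M810 among them, lay in block 2, which holds 98 spots. They included the brightest spot in the blocks, described below, and the spots listed just before and after it. These rises therefore cannot be taken as separate from one another.

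The brightest spot in the blocks, by mean over the 4 samples, rose by 2.61 on the log2 scale (limma adjusted p = 0.0195), by 1.33 and 3.01 in the WT pairs and by 1.58 and 4.51 in the KO pairs. Those ranked 2, 3 and 5 in brightness changed by 0.26, -1.80 and -1.22 (limma adjusted p = 0.863, 0.0780 and 0.253). The fourth brightest rose by 2.47 (limma adjusted p = 0.0232), by 1.83 and 3.23 in WT and by 0.66 and 4.14 in KO. KO minus WT was -0.56 at 3 h and 0.31 at 6 h for the brightest, and -0.12 and -0.25 for the fourth. These spots are described without IDs and were singled out after their values were seen. No spot of the 9 outside the blocks passed the test for time or genotype (lowest limma adjusted p 0.574 for time and 0.994 for genotype).

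The count of 16 depended on the settings. It was 0 with median scaling, with no scaling, with a 4 times smaller offset, with spots that had all 8 values and without genotype in the model. It was 42 with a 4 times larger offset, 49 with trend and robust variance options, 54 with values taken as already background-corrected and 56 when blanks were also set to 0; these held 16, 14, 15 and 16 of the 16 spots. With blanks set to 0 and the background correction kept it was 0. With block medians made equal across the arrays it was 67, 33 higher and 34 lower, which held all 16. With pairing by deposited ID it was 4. Leaving out 1 array changed it to 0 without the first KO 3 h array, 1 without the second WT 6 h array, 8 without the first WT 3 h array, 28 without the first KO 6 h array and 32 without the first WT 6 h array.

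Within WT, 59 spots met the size rule between 6 h and 3 h, 18 higher and 41 lower at 6 h. Within KO, 94 did, 43 higher and 51 lower. With pairing by deposited ID the counts were 34 in WT and 52 in KO, and with block medians made equal 63 and 84. With values taken as already background-corrected they were 31 in WT and 38 in KO. In block 6 the median time difference in KO was -1.38 in the first hybridisations, with 14.3% of 56 spots above 0, and -0.41 in the second. The direction in WT turned to 65 higher and 42 lower without the first 6 h array and 93 and 62 without the second, and was 19 and 86, or 63 and 111, without the first or second 3 h array. In KO it was 78 and 49, or 93 and 55, without the first or second 6 h array, and 70 and 111, or 40 and 89, without the first or second 3 h array. Over the 4 comparisons, in 16 of 16 such cases more spots were higher in the sample left with 1 array, for which the rule asks for only 1 value above the array median. The largest rise was 2.67 in WT and 5.16 in KO, and the largest fall was -4.42 in WT and -4.13 in KO, on the log2 scale; both falls rest on 1 array at 6 h. Exchanging the time labels of the second arrays gave 51 spots in each genotype, and splitting by set gave 83 in WT and 66 in KO. The hybridisations did not overlap in 31.2% of 552 spots in WT and in 39.0% of 546 spots in KO, against 33.3% for exchangeable arrays. Of the spots that met the rule in KO, 45.7% were higher at 6 h after quantile normalisation, 62.8% of 78 after median scaling, 14% of 107 after scaling on the last 9 spots and 9.57% of 115 without scaling. In WT 30.5% were higher, against 94.2% of 103 without scaling. The median difference of all spots in KO was 0.28, -0.68 and -1.03 under these 3 scalings, and in WT it was 1.05 without scaling and -0.13 after scaling on the last 9 spots.

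Time differences were partly shared between the genotypes. In both genotypes 6 spots met the rule upwards, where independent lists give 1.3, and 17 downwards, where they give 3.5. In opposite directions 0 met it, where they give 4.49. Part of the sharing above 1.3 and 3.5 is built in, since the rule draws both lists from bright spots. The 6 h minus 3 h differences of WT and KO, which share no array, correlated at r = 0.41 across 593 spots (95% interval 0.34 to 0.47; rho = 0.37), at r = 0.23 with pairing by deposited ID and at r = 0.49 with block medians made equal. By set, this was r = 0.16 (95% interval 0.07 to 0.24) in the first hybridisations and r = 0.41 (0.34 to 0.48) in the second. Between the sets, WT in the first against KO in the second gave r = 0.15 (0.07 to 0.23), and WT in the second against KO in the first gave r = 0.27 (0.19 to 0.35). The duplicates of 1 genotype correlated in their time difference at r = 0.08 (95% interval -0.0012 to 0.16) in WT and r = 0.13 (0.05 to 0.21) in KO. Each of the 4 arrays at 6 h differed from the 4 at 3 h in dynamic range, as given above.

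**Figure D3:**
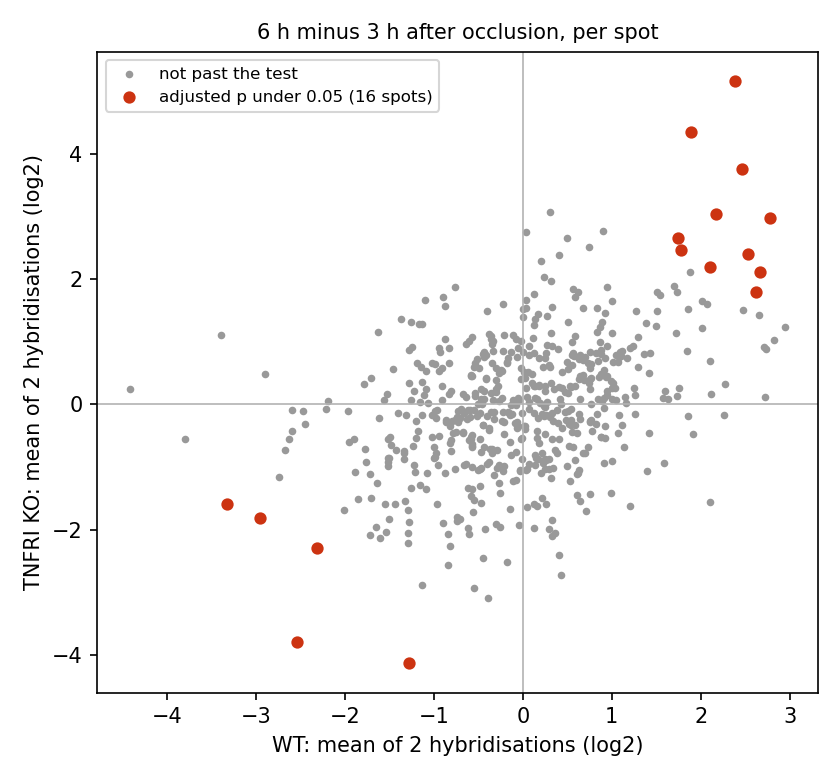
Difference between 6 h and 3 h per spot on the log2 scale in WT (x axis) and KO (y axis), each from means of 2 hybridisations. Red points are the 16 spots past the limma test over both genotypes, 11 above 0 and 5 below 0 on both axes; over all spots r = 0.41.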

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

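Of the tests in this part, that of unequal noise was written down before its result was seen, but after a cruder test of the same explanation, which held abundance at 6 h constant, had left r = -0.26; the tests of spot order, measurement noise, position on the array and exchanged labels were chosen after the correlations had been seen, and that of exchanged labels replaced an earlier void one after its own value was known. No group holds 4 samples, so no sample was tested for standing apart from its group.

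One spot met the size rule in opposite directions at 3 h and 6 h. KO minus WT was 1.15 at 3 h and -1.22 at 6 h on the log2 scale, a change of -2.38. The difference was not tested, since each group is 1 sample. Independent lists give 0.809 such spots, which is not a chance level, since the rule draws both lists from bright spots.

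The duplicates shared almost no signal by ID. Measurement noise is argued against by the arrays within a set, which correlated at r = 0.4846 or more between different samples. A different order of the spots within blocks accounts for the pattern, with r of at least 0.697 in every block once rows and columns are exchanged. What stays open is which set of files carries the right IDs, so any gene named from the authors' averaged table may belong to only one of the 2 spots averaged. No biological explanation was tested.

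KO minus WT at 3 h ran opposite ways in the 2 sets (r = -0.29 over the 508 spots with all values). Arrays of unequal noise would give a negative value too. The size predicted from covariances with the 6 h arrays was r = -0.03, leaving -0.261 (95% bootstrap interval -0.34 to -0.18). That prediction cannot take in signal shared only among the 3 h arrays, and the 6 h arrays differed from these in dynamic range. Unequal noise therefore stays open as a cause of the remainder. Uneven signal over the array was present, with 47.7% of the variance of the first difference between blocks, but with block, row and column effects removed r was -0.2334 (95% interval -0.32 to -0.15), which argues against it as the whole cause; pairing by ID, which joins different spots of a block, gave r = -0.15, and -0.07 (95% interval -0.15 to 0.01) with block effects and -0.04 (-0.13 to 0.06) with all 3 removed. The second KO 3 h array had the highest median intensity of all arrays. Paired by position, it correlated at r = 0.39 to 0.50 with the 6 h arrays. Whether this array alone gave the pattern was not tested. An exchange of the KO and WT labels in one set at 3 h is another candidate explanation that stays open. Crossed differences at 3 h correlated with KO minus WT at 6 h at r = -0.0848 (95% interval -0.16 to -0.0043), which decides nothing, since KO minus WT at 6 h did not itself clearly repeat between the sets (r = -0.06, 95% interval -0.14 to 0.03); a genotype difference at 3 h stays untested.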

How the results depend on the processing

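No paired analysis was possible because each group holds 1 sample. The files number the 2 hybridisations of a sample. A fit kept the 8 hybridisations apart, with that number as a factor and the sample as a block. This fit gave 0 spots for KO and WT and 60 for time. Its consensus correlation of duplicates was -0.445, so that duplicates were no more alike than other arrays. A negative correlation makes the SEs smaller than those of independent arrays, and the 60 calls for time rest on technical repeats. The count of spots past the test for KO and WT was 0 in 15 of 19 settings and 1 with the first hybridisations only, trend and robust variance, or values taken as corrected, with blanks left out or set to 0. Leaving out 1 array gave 0 to 1. The count for time, 16, became 0 with median scaling, no scaling, a smaller offset, no second factor, the authors' table, blanks set to 0 alone or spots with all 8 values, 2 with the first hybridisations only, 4 with pairing by ID, 9 with scaling on the last 9 spots, 34 with spots above the median only, 42 with a larger offset, 49 with trend and robust variance, 54 with values taken as corrected, 56 with blanks also set to 0 and 67 with block medians made equal. Leaving out 1 array gave 0 to 32 for time. Each sample was left out only together with the second factor. The size-rule counts were 30 (KO and WT, 3 h), 33 (6 h), 59 (time, WT) and 94 (time, KO). With 1 array per sample the rule's separation is met more easily by construction, and the counts, in that order, were 191, 140, 225 and 178 with the first hybridisations and 144, 61, 121 and 199 with the second; leaving out 1 array gave 30 to 143, 33 to 131, 59 to 174 and 94 to 181, with more spots higher in the sample left with 1 array in 16 of 16 cases. The authors' table, with no overlap criterion, gave 49, 59, 152 and 190. A 3-fold rule gave 6, 8, 30 and 45, and a 1.5-fold rule 54 and 58 for genotype. Blanks set to 0 alone gave 30, 35, 64 and 92, values taken as corrected 4, 5, 31 and 38, and both together 6, 6, 36 and 42. Pairing by ID gave 28, 21, 34 and 52, and block medians made equal 16, 22, 63 and 84. Scaling on the last 9 spots gave 60 and 14 for genotype, no scaling 125 for genotype at 3 h and 103 for time in WT, and spots above the median 19 for genotype at 6 h; the causes were not tested. The named spots M810, M309, M518 and M362 lost their call in 13 of 28, 13 of 28, 14 of 28 and 16 of 26 settings, with changes from 2.35 to 4.74, 1.07 to 5.16, -5.56 to -0.78 and -3.74 to -0.97; none reversed. The settings counted for the named spots include the fits without a sample and without the second factor. Those fits leave 1 sample in a group and could hardly give a call. The correlation of time differences in WT and KO ran from 0.16 to 0.55, and that of genotype differences between the sets at 3 h from -0.34 to -0.14, over their alternatives. Planned gene lists and housekeeping scaling were not run, since no IDs could be matched to genes.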

Other observations

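The test of abundance was written down before its result was seen; the other 2 tests here were chosen after the within-set correlations had been seen.

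The cause of the time difference shared by WT and KO is not settled. Differences that belong to a hybridisation set would not repeat between sets, but WT in one set and KO in the other correlated at a mean r of 0.2157 across 508 spots (95% bootstrap interval 0.1517 to 0.28), which argues against the set as the whole cause. A change in the tissue stays open: the lower bound of 0.1517 lies above 0, but the same genotype repeated between sets only at r = 0.08 (95% interval -0.0012 to 0.16) in WT and 0.13 (0.05 to 0.21) in KO, below the value for WT against KO, and an exchange of labels at 3 h would make the differences across sets share a 3 h sample. The dynamic range of the 6 h arrays, signal from bright neighbours and other handling also stay open, since they go with time; holding abundance constant left 0.22 (95% bootstrap interval 0.16 to 0.28), above the 0.05 set beforehand, but it moved nothing after quantile normalisation and so is no test. A split of the 4 samples by time alone, with 2 residual degrees of freedom, gave 0 spots past the limma test and 106 at an unadjusted p under 0.05, against 0 and 5 for the split by genotype and 0 and 6 for the remaining split.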
